A study of Saccharomyces cerevisiae and Saccharomyces paradoxus with 173 samples.

How the data were processed

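The series holds RNA samples of budding yeast, each hybridised to spotted oligonucleotide arrays in 2 colours. Per the labels' protocols, 1 culture of each of 10 natural strains was arrested in late G1 with the mating pheromone alpha factor, released at a low temperature in minimal medium and sampled at up to 18 times from 0 to 345 min. The other channel held a common reference, RNA of unsynchronised cells of strain YPS183 grown in rich medium. The labels name 377 arrays, 1 to 5 per sample, and the deposited values give 1 column per sample with dye swaps already combined by the authors. How the arrays of a sample were combined and normalized is not given in the sources used here.

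The deposited values, treated here as log2, are log ratios that the authors made by combining each sample's GenePix arrays over dye swaps, per the labels. The base of the logarithm is not stated in the sources used here, so the sizes given hold only if it is 2. The direction of the ratio is likely sample over reference: pheromone-induced AGA1 and FIG1 were high at 0 min in several strains. The scale and centring stay unknown beyond this, with sample medians from -0.066 to 0.039. Single values ran from -16.92 to 9.87, 549 of them beyond 8 in size. Whether the arrays can measure ratios that large was not checked. The normalized table held 6172 genes and was used throughout; the series matrix held 6161 of them with identical values. No value was missing. Of the gene identifiers, 5554 matched the RefSeq table of assembly R64 directly, 192 after a hyphen was restored, and 426 did not match and keep the name in the table. A further 7 columns of the normalized table matched no sample and were not used. Many identifiers belong to near-identical copies (Ty elements, Y' helicase genes, ASP3 genes), whose probes cannot tell the copies apart. Array number limits the precision: 8 samples rest on 1 array, 132 on 2 and 33 on more. Signal over background was not analysed here.

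Samples were grouped by strain, with sampling time as a number. There was 1 culture per strain, so p-values within a strain do not cover the spread between cultures. They rest on the scatter of time points around smooth curves, estimated once per gene over all strains. A strain with more or less scatter than the rest is judged by that shared estimate. The labels also give the print year of the arrays: 133 samples have 2007 for every array whose year is given, called 2007 prints alone here, and 40 on some prints of 2005 or 2006, of which 17 are YPS2073, 9 YPS3060, 9 YPS3137 and 5 YPS183. For YPS2079 at 111 min, counted among the 133, the year of 1 of 3 arrays is not given. In YPS3060 and YPS3137 all 9 such samples fall on alternate sampling times (0, 48, 87, 135, 176, 218, 251, 284 and 325 min), called set A here; the other times are set B.

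Tests used limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 24 min samples were compared with the 0 min samples over 10 strains, with strain as a block. Time courses were fitted in 1 model with strain and a strain-specific natural spline of time with 7 degrees of freedom, and a size of at least 1 on the log2 scale was also required. In that model each strain's mean over the 12 times shared by all strains, and the shape of its curve with the level removed, were compared with the mean of the other S. cerevisiae strains. YPS3395, labelled S. paradoxus, was compared with the 9 S. cerevisiae strains on 1 mean per strain. The 23 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and list means were put through the same spline model. Timing was measured per gene as the shift between -60 and 60 min, in steps of 3 min, that gave the highest correlation with the mean profile of the other S. cerevisiae strains. Lists were then compared by a two-sided permutation test of medians with 100000 resamples, with bootstrap intervals from 10000 resamples of genes. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for the rest.

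Gene lists, tests and the rule for named genes were fixed before the data were examined. The rule names the 12 largest rises and 12 largest falls between 0 and 24 min that went the same way in all strains, the 3 highest and 3 lowest genes of each strain, the 3 largest differences of time course in each strain, the 12 highest and 12 lowest genes between species, 8 cell cycle landmarks, and up to 4 members of each list. Some genes and 1 gene list that the rule takes are not reported here. Its part for time courses asked for genes varying in at least 9 strains; 0 genes did, the highest number being 6, and the 18 genes that passed the adjusted p in at least 5 strains are named in their place, chosen after their values were seen. The planned timing analysis asked for genes varying in the strain and in 5 others; it left 0 list genes, so timing is given for all measured list members.

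On simulated data with 6172 genes, a level difference of 1.5 in 1 strain was recovered for 200 of 200 genes with 0 false calls, a time course of amplitude 1.5 for 198 of 200 with 2 false calls, a differing time course of that amplitude for 197 of 200 with 0 false calls, and a change of 1 between 0 and 24 min for 190 of 200 with 10 false calls. These simulations hold independent errors and no batch. A simulated shift of 30 min in 20 genes gave a median lag of 30 min. Alternatives covered scaling, the table used, spline flexibility, array prints, dye swaps, weights, baselines and left-out strains or times; the closing section gives their effect.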

Results

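The data were log2 ratios of 6172 genes in samples of 10 natural yeast strains, 9 labelled Saccharomyces cerevisiae and YPS3395 labelled S. paradoxus, followed from release of a pheromone arrest to 345 min. Most strains had 18 samples; YPS2060 had 15, and YPS2067 and YPS3137 had 16 each. Each sample rested on 1 to 5 arrays. The series title names changes in the timing of transcription, and the design gives comparisons over time, between strains and between species. The median over samples of the spread of all genes' log2 ratios was lowest in YPS183, at 0.51, and highest in YPS2073, at 1.06.

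The first comparison asked which genes changed between 0 and 24 min after release. RNR1, the large subunit of ribonucleotide reductase, rose by 2.05 ± 0.30 (SE, n = 10 strains, limma adjusted p = 0.0057), and the replication clamp POL30 rose by 1.06 ± 0.13, both in 10 of 10 strains. The mannosyltransferase MNN1 rose by 1.18 ± 0.12 and the cell wall transglycosylase UTR2 by 1.26 ± 0.13. PUN1 fell by 1.20 ± 0.18, the cell surface protease YPS1 fell by 1.16 ± 0.16, the hexokinase HXK1 fell by 1.11 ± 0.22 and the glycogen branching enzyme GLC3 fell by 1.08 ± 0.18, each in 10 of 10 strains. In all, 257 genes passed the limma threshold, 151 higher and 106 lower at 24 min, and 13 of them changed by at least 1.

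The rest of the 12 largest rises seen in all strains were RFA2 (0.88), RPS28B (0.86), APT1 (0.85), NOC2 (0.77), the G1 cyclin PCL1 (0.76), RPA135 (0.72), NUG1 (0.68) and SKG6 (0.68). The rest of the 12 largest falls seen in all strains were TPS2 (-0.91), YMR315W (-0.87), PHD1 (-0.84), ORM2 (-0.71), YGR122C-A (-0.66), FAA1 (-0.65), PAL2 (-0.64) and YLR177W (-0.62).

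Of 30 measured genes of the G1/S replication and repair list, 14 rose and 0 fell, and 25 rose when adjusted over the list alone. RNR1, POL30 and RFA2 were among them. In the G1/S budding list 5 of 22 rose, led by MNN1 and PCL1, and 8 rose when adjusted over the list alone. Among 10 early M/G1 genes with an early cell cycle box, 5 rose, including MCM6 (0.59), CDC6 (0.41), MCM3 (0.39) and SWI4 (0.38). In the ribosome biogenesis list 5 of 22 rose, such as UTP10 (0.73), and 13 did so when adjusted over the list alone; NSR1 stood at 0.90 with adjusted p = 0.105. Of 27 pheromone response genes 4 fell, including AGA2 (-0.98) and MFA2 (-0.97), and 10 fell when adjusted over the list alone. The median of that list was lower at 24 min in 9 of 10 strains and 0.52 higher in YPS3060, whose 0 and 24 min samples also differ in array prints. AGA1, the anchor of the mating agglutinin, had a mean change of -1.17, with adjusted p = 0.212. In the hexose list 3 of 11 fell, among them HXT1 (-1.57), and 7 did so when adjusted over the list alone. Of 22 stress genes 4 fell, including GPD1 (-1.42), GLC3, TPS2 and PGM2 (-0.78). By camera with the preset correlation, the replication (adjusted p = 1.62e-23), ribosome biogenesis (4.43e-11), pheromone (5.57e-09), stress (1.22e-06) and hexose (3.36e-06) lists were past the threshold, as were the budding and early cell cycle box lists. The G2/M list was also past it, with a median of -0.14 at 24 min (adjusted p = 0.0103; 0.553 with an estimated correlation) that turned to 0.14 at 48 min (adjusted p = 0.0019; 0.273 with an estimated correlation). With an estimated correlation 0 lists were past it at 24 min, with 5 at an unadjusted p under 0.05: the lowest adjusted p was 0.0785, which the replication, ribosome biogenesis and early cell cycle box lists had. It was 0.211 for the hexose, 0.225 for the stress and 0.306 for the pheromone list.

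Histone genes did not pass the limma threshold at 24 min (0 of 9, and 0 at an unadjusted p under 0.05, median 0.09), and their median was 1.36 higher at 48 min than at 0 min (camera adjusted p = 8.33e-13; adjusted p = 0.171 with an estimated correlation). The 0 and 24 min samples belong to different sets of alternate sampling times, which in YPS3060 and YPS3137 also differ in array prints. Comparing 48 min with 0 min, both of set A, 236 genes passed. Of the 257 genes called at 24 min, 76 also passed at 48 min in the same direction, and 253 had the same sign. Both comparisons use the same 0 min samples. In the 6 strains whose 0 and 24 min samples have both dyes and 2007 prints 89 genes passed, and in the 4 strains with at most 4 genes differing between the sets, picked on these data, limma called 0 genes, with 711 at an unadjusted p under 0.05.

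Pheromone genes were not high at 0 min in every strain. AGA1 was at 3.05 in YPS3395, 2.89 in YPS183, 2.43 in YPS2066, 2.03 in YPS2055 and 1.89 in YPS2067, but at -1.16 in YPS2073 and -2.21 in YPS3060. FIG1, a mating gene induced by pheromone, was at 3.48 in YPS183 and at -0.06 in both YPS2073 and YPS3395. FUS1 was at 0.99 in YPS183 and 0.09 in YPS3395. Each of these is 1 sample with no replicate check. Of the 0 min samples, only those of YPS2073, YPS3060 and YPS3137 used some older prints. AGA1 was at 0.14 in YPS3137, and at 0.26 in YPS2060 on 2007 prints. In YPS3060 AGA1 was at 0.82 at 24 min, of set B, and at -3.24 at 48 min, of set A. For the low AGA1 values of YPS2073 and YPS3060, strain and array print cannot be told apart.

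Genes varying with time numbered 512 in YPS2067, 422 in YPS2066, 364 in YPS2073, 316 in YPS3395, 213 in YPS2055, 188 in YPS183, 96 in YPS3137, 82 in YPS3060, 32 in YPS2079 and 9 in YPS2060. RNR1 varied in 5 strains, with a fitted range of 4.65 in YPS2067 and 4.31 in YPS2055 and a fitted peak at 63 min in both. The mitotic cyclin CLB2 varied in 4 strains, by 3.03 with a peak at 194 min in YPS2066, 3.02 at 176 min in YPS2067 and 2.95 at 218 min in YPS2055. The histone gene HTA1 varied in 4 strains, with fitted peaks at 111 min in YPS2055 and YPS2066, 87 min in YPS3395 and 325 min in YPS183, where its range was the highest of the 4 (3.79). The G1 cyclin CLN2 varied in 4 strains, SWI5 in 3 and FUS1 in 2; SIC1 and CTS1 did not pass in any strain (lowest adjusted p 0.115 and 0.211).

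Scrambling the times within each strain gave as many genes as the real order in none of 99 scrambles for YPS2055, YPS2066, YPS2067, YPS2079 and YPS3395. The median scrambled count was 1 in YPS2055, 3 in YPS2067 and 5 in YPS2066 and YPS2079. In YPS3395 it was 119, with 292 the highest, against the real 316. In the other strains some scrambles reached the real count. Counting the real order, 6 of 100 orders in YPS183, 12 in YPS2060, 36 in YPS2073, 90 in YPS3060 and 99 in YPS3137 did so. Scrambles were not run with the term for alternate sampling times, and a count that scrambles reach does not show that single genes or lists lack a time course. Where a gene or list is said to vary in 1 of these 5 strains, it passed limma in a strain whose count scrambled times also reach. With a term for alternate sampling times the counts were higher, at 865 in YPS2067, 381 in YPS2055, 438 in YPS183, 327 in YPS3060 and 347 in YPS3137. A fit on 2007 prints alone left out YPS2073, YPS3060 and YPS3137. It gave 1051 in YPS2067, 738 in YPS2066, 539 in YPS2055, 539 in YPS3395 and 146 in YPS2079. These strains had 2007 prints alone from the start, so their own samples did not change. The residual spread per gene, shared by all strains of a fit, was then estimated without the strains left out.

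HSP31, a chaperone of the DJ-1 family, varied in 6 strains, and AGA1, MFA2, CSS1, NCE102, ZRT1, YAR068W, DAL5, HTB2, RNR1, GSC2, GOR1, GLY1, POL30, RSN1, NRE1 and KES1 in 5 each; TVP23 passed the adjusted p in 5 strains and the size in 3. These genes were chosen after their values were seen.

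In YPS2055 the mean of the replication list had its fitted peak at 63 min, histones at 111 min and the G2/M list at 218 min (limma adjusted p of the list means 2.97e-06, 0.0015 and 4.87e-05). In YPS2067 these peaks were at 63, 135 and 176 min, and in YPS2066 at 111, 111 and 301 min. The mean of the pheromone list passed limma with a fitted peak at 0 min in YPS2055, YPS2066, YPS2067 and YPS2079, and in YPS183 and YPS2060, where scrambled times reached the count of varying genes. The iron uptake list varied in YPS2055, YPS2066 and YPS2067, with a fitted range of 1.79 in YPS2066, where 12 of 15 genes varied.

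**Figure D1:**
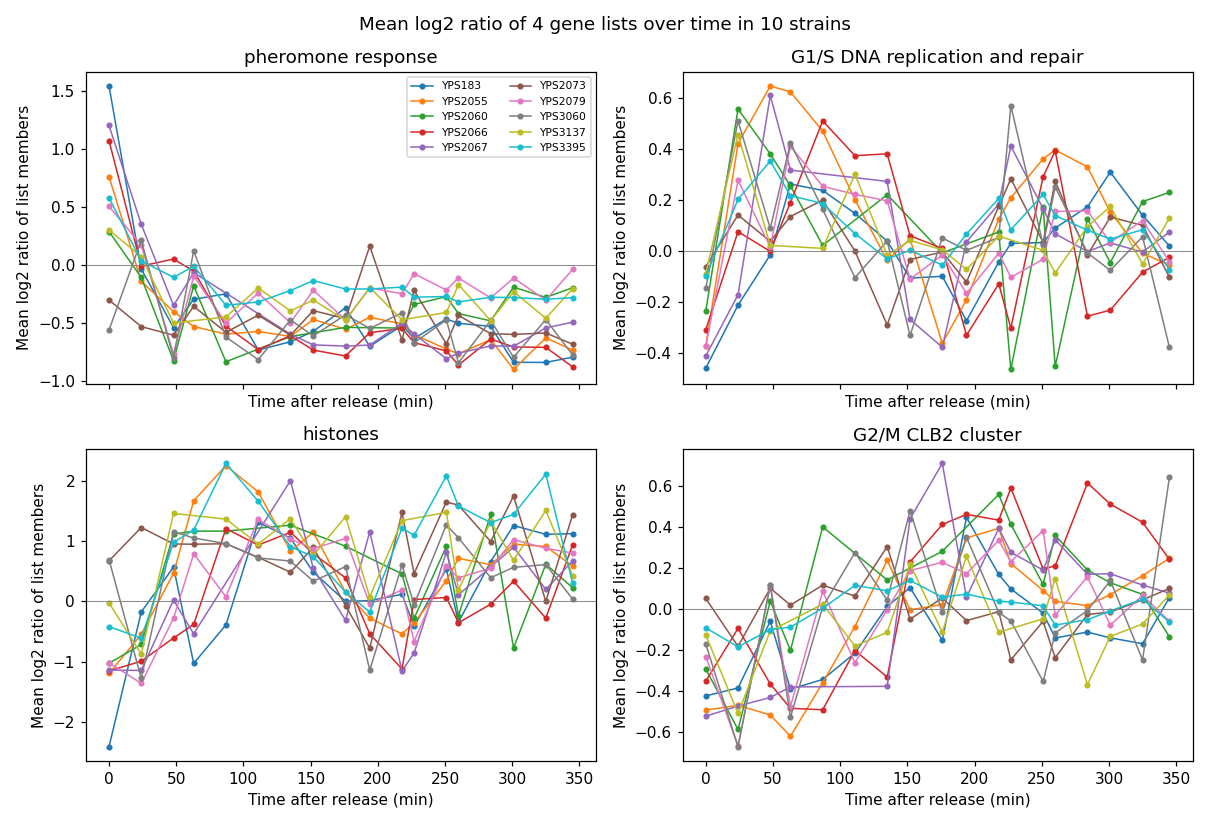
Mean log2 ratio of the members of 4 gene lists against time after release in minutes, with 1 line per strain and 1 point per sample. Histone means in YPS2055 run from -1.19 at 0 min to 2.25 at 87 min, and the pheromone mean in YPS183 is highest, 1.54, at 0 min.

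Shifts in timing were asked of 7 cell cycle lists in each strain. The planned test could not be made, since 0 list genes varied in enough strains. With all measured members, the G2/M list in YPS2066 had a median lag of 52.5 min behind the other S. cerevisiae strains (95% interval over genes 30 to 58.5). The other lists together ran 30 min late there (permutation test, adjusted p = 0.0325 over 70 tests). In YPS2055 the G2/M lag was 7.5 min (-9 to 25.5, which includes 0) against -9 min (permutation test, adjusted p = 0.0257). The lag of the list's mean profile was 60 min in YPS2066, the edge of the range searched, and -9 min in YPS2055. The size of the shift is thus not settled in either strain. The G1/S budding list had a median lag of 39 min in YPS2060 (-3 to 51) against -3 min (permutation test, adjusted p = 0.0119), but 0 of its 22 genes varied with time there by limma, nor did its mean (adjusted p = 0.355), so this is not given as a shift in timing. With fitted splines in place of samples 0 of the 70 pairs passed, with 15 at an unadjusted p under 0.05, and leaving out 1 time at a time gave between 1 and 7. Over those 18 runs the G2/M lag ran from 27 to 57 min in YPS2066, passing in 4, and from -9 to 10.5 min in YPS2055, passing in 10, and the budding lag in YPS2060 ran from -22.5 to 51 min, passing in 8. Genes of a list share the samples' errors and are not independent replicates.

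In level over the shared times, YPS183 had 157 genes higher and 48 lower than the other S. cerevisiae strains; the Ty element frames YML045W, YLR227W-B and YBL101W-B were 4.41 ± 0.34, 4.39 ± 0.39 and 4.31 ± 0.35 higher (SE of the fit, 1 culture), and the asparaginase gene ASP3-3 was 3.22 ± 0.21 higher. Of 39 copy number variable and subtelomeric genes 8 were higher and 2 lower there (camera adjusted p = 2.60e-06; adjusted p = 0.1 with an estimated correlation). YHR214W-A (-2.46), the allantoate permease DAL5 (-2.29) and the carboxypeptidase CPS1 (-2.16) were its lowest. In YPS183, 26 of 30 respiratory chain genes passed the adjusted p and were lower, 9 by at least 1, led by CYC1 (-1.80) and CYT1 (-1.67); the list median was -0.78 (camera adjusted p = 3.43e-22; 0.0273 with an estimated correlation). The reference RNA is also from YPS183, so its own ratios compare 2 growth conditions of 1 strain and those of other strains also compare strains.

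YPS2066 was higher in iron uptake genes. Of 15 measured, 9 were at least 1 higher, with the siderophore transporters ENB1 (1.93 ± 0.09), ARN2 (1.77 ± 0.12) and ARN1 (1.38) and TIS11 (1.29); the list median was 1.04 (camera adjusted p = 5.95e-31; 7.05e-07 with an estimated correlation), and 1.21 and 0.85 within sampling sets A and B. IRC7 was 1.98 ± 0.11 higher there, and the Y' frames YIL177C (-2.34), YLL067C (-2.21) and YBL113C (-2.20) were lowest.

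YPS2073 was higher in ribosomal protein genes. Of 138 measured, 55 were at least 1 higher and 0 lower, with RPL14B (2.76 ± 0.17), RPL23A (2.63), RPP2B (2.18) and RPS13 (2.07); the list median was 0.86 (camera adjusted p = 1.23e-62; 0.0023 with an estimated correlation) and 0.62 after quantile normalization. All but 1 of its samples used older prints. YHR214W-A (2.83) and the ammonium permease MEP2 (2.82) were also high, and the Ty frames YJR028W (-6.40), YOL103W-A (-6.25) and YDR210C-C (-5.63) were lowest. The mean levels of these frames in YPS2073 were -10.9, -10.8 and -10.3, so extreme that the size of their differences is uncertain. Its 91 higher and 111 lower genes became 28 and 20 after quantile normalization; in YPS183 that scaling gave 120 and 106.

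YPS2055 had 16 genes higher and 16 lower, with YIL080W (1.36), YRF1-4 (1.29) and YRF1-6 (1.25) against HXK1 (-1.74), the amino acid permease AGP1 (-1.45) and YMR194C-A (-1.42). YPS2060 had 2 higher and 4 lower, with YNL054W-A (1.16) and HSP12 (1.10) against the zinc transporter ZRT1 (-1.34), AGP1 (-1.09) and GPM1 (-1.07). YPS2067 had only YMR194C-A (-1.10). YPS2079 had 6 higher and 36 lower, with SNZ3 (1.67), SNZ2 (1.60) and IRC7 (1.41) against YBL113C (-2.13), YRF1-1 (-2.04) and YLL067C (-2.01). YPS3060 had 6 higher and 12 lower, and YPS3137 had 17 and 96. With each sampling set fitted alone, 0 higher and 0 lower genes were called in both sets of YPS3060, and 5 higher and 0 lower in both sets of YPS3137. In YPS3060 YMR046W-A (1.64), YGR122C-A (1.60) and YCR018C-A (1.43) were highest and EKI1 (-2.24), IBD2 (-2.09) and KGD2 (-1.89) lowest; in YPS3137 TIP1 (1.80), YRF1-7 (1.49) and AGP1 (1.43) were highest and IBD2 (-3.27), YNL165W (-3.24) and PIM1 (-3.20) lowest. Within set B of these strains EKI1 and IBD2 differed by 0.0151 and 0.0425 in YPS3060 and PIM1 by 0.061, AGP1 by -0.18 and TIP1 by 0.33 in YPS3137. Mean set B levels, a measure separate from the differences just given, were for KGD2 0.412 in YPS3060 and 0.415 in the other S. cerevisiae strains. Those of YNL165W were 0.095 in YPS3137 and 0.107 in the others. Against YPS183 alone TIP1 (-0.27), YRF1-7 (-0.62) and AGP1 (-1.51) turned in YPS3137, YRF1-4 (-0.70) and YRF1-6 (-0.92) in YPS2055, and YNL054W-A (-0.15) and ZRT1 (0.19) in YPS2060. The correlation across genes of level differences between both sets was -0.27 in YPS3060, 0.02 in YPS3137, 0.17 in YPS2060, 0.49 in YPS2067 and between 0.61 and 0.92 in the other 6 strains (genes are not independent replicates). Sets also differed by limma in 398 genes in YPS2079 and 197 in YPS2060, strains with no known older prints. In YPS2073 they differed in 1399 genes. Both sets of YPS2073 hold older prints, but its arrays printed in 2005 fall only in set A, so print year partly separates its sets. With an estimated correlation 3 list calls held over all strains, those given above for YPS183, YPS2066 and YPS2073.

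Differences in the shape of the time course numbered 199 genes in YPS2073, 115 in YPS3395, 78 in YPS2067, 61 in YPS2066 and 23 in YPS183 as deposited, and 74, 195, 78, 31 and 417 after quantile normalization, so the strains have no fixed order. The values given next are the largest deviations of a gene's curve from that of the other strains once each curve is centred on its own mean, so they leave out differences in level. In YPS2066 the deviation was -2.43 at 24 min for IRC7, 2.41 at 48 min for the pheromone gene MFA1 and 2.00 at 0 min for BAR1. In YPS183 it was 2.81 at 0 min for SLD3, a replication initiation factor, -2.38 at 48 min for ARG1 and -3.21 at 260 min for COA1. In YPS3395 it was 4.10 at 0 min for GPM1, 3.90 at 0 min for YBL005W-A and -2.96 at 251 min for RPP0. Ty frames had the largest deviations in YPS2073, with YDR261C-C (7.56), YJR028W (4.99) and YGR161C-C (-4.62), and in YPS2067, with YDR098C-A (3.34), YMR045C (3.20) and YDR365W-A (2.89). The leading genes elsewhere were YLR434C, YML084W and ARN2 in YPS2055, CCC1 in YPS2060, YGL102C and YEL067C in YPS2079, BFR2, DCK1 and VTS1 in YPS3060, and LAF1, MPC54 and YBR184W in YPS3137. When strain labels were scrambled within times, 57 of 100 orders reached the count of 3 in YPS2055, 97 the count of 1 in YPS2060, 57 the count of 2 in YPS2079, 14 the count of 31 in YPS3137 and 6 the count of 25 in YPS3060, the real one included.

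Between species, YPS3395 was higher in 23 genes and lower in 46 by limma on 10 strain means. That split turned to 59 higher and 45 lower in the 7 strains with enough samples on 2007 prints, and to 55 and 54 without YPS2073. Leaving out any other S. cerevisiae strain kept more lower than higher genes. The peroxisomal citrate synthase CIT2 was at 0.31 in YPS3395 and 3.32 ± 0.49 (SD, n = 9 strains) in S. cerevisiae, a difference of -3.01 (limma adjusted p = 0.0107). Enolase ENO1 (-2.46), fatty acid synthase FAS1 (-2.36), VOA1 (-2.27), SIM1 (-2.22), SCW4 (-2.13), SRL1 (-2.02), COX6 (-1.94), HSP150 (-1.90), YOR248W (-1.89), the sulfite reductase subunit MET10 (-1.88) and YLL020C (-1.87) were also lower. RPS18B (1.69), PMP2 (1.55), RPL7A (1.54), RPL33A (1.46), PRY2 (1.43), ARO9 (1.35), MTD1 (1.30), PHO3 (1.27), ARO10 (1.25), VMA16 (1.21) and SEC53 (1.19) were higher.

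Of 138 ribosomal protein genes 8 were higher and 1 lower in YPS3395, and 22 and 2 when adjusted over the list alone (median 0.51, camera adjusted p = 5.32e-11; adjusted p = 0.750 with an estimated correlation). In the sulfate and methionine list 3 of 21 were lower (median -0.65, camera adjusted p = 4.25e-09; adjusted p = 0.237 with an estimated correlation). Only 1 S. paradoxus strain was measured. Taking YPS3137 as the odd strain in the same test gave 105 genes and YPS2073 gave 28, against 69 for YPS3395. The level differences of YPS3137 hardly correlated between its sampling sets (0.02).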

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

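The tests of array prints and of the reference strain were chosen after the result was seen; the tests of change over time, of probe sequence, of the spread between strains and of scrambled samples were written down before. Of 47 groups of 10 strains examined for 1 sample far from the others, 1 stood out, where chance gives about 1 in 20: YGR122C-A changed by -1.94 between 0 and 24 min in YPS2073, with the next strain at -0.90.

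Mean time courses of lists differed from the other S. cerevisiae strains in 14 of 230 tests of the difference itself (limma). For the pheromone list the adjusted p was 0.0102 in YPS183, 0.0457 in YPS2066, 0.0222 in YPS2067, 0.0102 in YPS2073 and 0.028 in YPS3060. For the G1/S budding list it was 0.0037 in YPS2066, and for the replication list 0.0457 in YPS2060 and 0.0329 in YPS2066. For the G2/M list it was 0.0188 in YPS2066 and 0.0102 in YPS2073. For ribosomal proteins it was 0.0011 in YPS2067 and 0.0262 in YPS2073, and for iron uptake 0.0106 in YPS2060 and 3.73e-10 in YPS2066.

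Sampling sets differed in 2413 genes in YPS3060 and 2589 in YPS3137 by limma, 327 and 405 of them by at least 1. Of these, 9 genes were at least 2 lower at set A than at set B times in both strains. Their median difference was -3.96 in YPS3060 and -5.88 in YPS3137, and in the other strains it lay between -0.13 and 0.10. A difference between array prints may be involved, since these set A samples all use older prints. In YPS183 the same genes differed by a median of -0.218 between 5 older-print and 4 newer samples of set A (interval of the median -0.815 to -0.050), which does not decide it by the bounds set. The 17 older-print samples of YPS2073 were at a median of 0.02, against -3.71 in those of YPS3060 and -5.95 in those of YPS3137. For these 9 genes this argues against an effect of print year alike in all strains. An effect of prints confined to YPS3060 and YPS3137 stays open. Change of the cells over time was tested by the correlation of neighbouring times, -0.741, but the genes were picked for alternating, so that test is void. Print and sampling set cannot be told apart within these 2 strains.

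In YPS3395, 46 of 69 called genes were lower, though the excess of lower genes was lost on 2007 prints (59 higher, 45 lower) and without YPS2073 (55 and 54). It stayed when any other S. cerevisiae strain was left out, with 32 higher and 72 lower without YPS183. After quantile normalization it was 33 and 58. A strain variant against the array sequence may weaken binding for the lower genes. The test assumed that such a probe flattens the profile, though a loss by a constant factor would leave the SD of log ratios unchanged. The median difference of SD over time from S. cerevisiae was 0.147 (interval -0.034 to 0.271), which does not decide it. For the 23 higher genes it was 0.2045 and for all genes 0.0147. The spread between strains stays open too: 2 of the 10 strains, YPS3395 included, gave at least as many genes when taken as the odd one, and with 10 strains a share under 0.05 is out of reach. The other strain was YPS3137, with 105 genes, 101 of them lower, and YPS2073 came next with 28. In the spline model YPS3137 had 179 lower genes in set A and 11 in set B, with 0 shared. Its count may therefore reflect the sampling sets and is a poor measure of the spread between strains. A species difference stays among the open explanations, as untested.

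The 205 genes called in YPS183 had a median absolute level of 0.695 there and 2.44 in the other strains, and 191 of them lay nearer 0 in YPS183. A candidate explanation is that the reference RNA came from the same strain. The bound set for it, a level under 0.5, was not met. The test cannot decide it, since a difference between strains can also put YPS183 nearer 0 against RNA of its own strain. All strains share the reference, so with exact log ratios it cancels in the level difference itself. A biological difference between strains stays open.

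Chance was tested by regrouping the samples 100 times, the real grouping included. For the change between 0 and 24 min 1 grouping, the real one, gave 257 genes, and the highest other gave 2. For levels the real total of 911 was reached by 1 grouping, itself, with 51 the highest other; for differing time courses 538 was reached by 1, with 268 the highest other. For genes varying with time 3 of 100 orders reached the real total of 2234, the highest other being 2380 and the median 1287. Each real total was thus reached in under 0.05 of the regroupings. For levels and differing time courses, single samples were moved between strains, which breaks up each culture. With 1 culture per strain, chance differences between cultures were not tested and are not excluded. For time the scrambled counts were high in some strains, with medians of 488 in YPS3137, 328 in YPS2073 and 224 in YPS3060. The fit shares 1 estimate of residual spread per gene over all strains. Why these counts are high was not tested. The time total also hides that in 5 strains scrambled times reach the real count.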

How the results depend on the processing

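The alternatives with 48 min, with strains picked for small set differences, with a term for or within sets of alternate sampling times, with left-out strains or times, with 2007 prints between species, and all timing settings beyond the gene choice fixed before were chosen after seeing the data. The cause of each change was not tested. Strain was the pairing, as a block, between 0 and 24 min; without the block 138 genes passed in place of 257. Strains with both dyes and 2007 prints gave 89, eBayes with trend and robust options 389, and a change of at least 1 gave 13. The 4 strains with at most 4 genes differing between sampling sets gave 0 genes by limma, with 711 at an unadjusted p under 0.05; fewer strains were tested. Leaving out each strain gave 137 (without YPS2060) to 531 (without YPS2073), with 138 without YPS2079, 153 without YPS3060, 157 without YPS2055 and 159 without YPS3137. With an estimated correlation 0 lists passed between 0 and 24 min, 5 doing so at an unadjusted p under 0.05, and 3 passed for levels. At 48 min the G2/M list median turned to 0.14. Between species the spline contrast gave 235 genes, 2007 prints 104, and leaving out each strain 42 (without YPS2079) to 109 (without YPS2073), with 104 without YPS183. Timing gave 4 list and strain pairs with all members, 1 with lags to 45 min, 5 against YPS183, 5 with corrected profiles, 0 with fitted splines (15 at an unadjusted p under 0.05), and 1 to 7 leaving out each time.

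With no size threshold the counts were for level 1948 (YPS183), 502 (YPS2055), 385 (YPS2060), 947 (YPS2066), 468 (YPS2067), 2033 (YPS2073), 731 (YPS2079), 813 (YPS3060), 2020 (YPS3137), 2442 (YPS3395), 12289 (all strains) and for time course 53 (YPS183), 2 (YPS2060), 128 (YPS2066), 200 (YPS2067), 559 (YPS2073), 4 (YPS2079), 62 (YPS3060), 59 (YPS3137), 267 (YPS3395), 1338 (all strains). Quantile normalization gave for varying with time 1107 (YPS183), 22 (YPS2060), 248 (YPS2066), 127 (YPS2073), 627 (YPS3395), for level 15 (YPS2055), 21 (YPS2060), 2 (YPS2067), 48 (YPS2073), 33 (YPS3060) and for time course 417 (YPS183), 0 (YPS2055), 31 (YPS2066), 74 (YPS2073), 42 (YPS3060), 195 (YPS3395), 879 (all strains). A spline with 5 degrees of freedom gave for varying with time 36 (YPS2060), 149 (YPS3137) and for time course 14 (YPS183), 1 (YPS2055), 0 (YPS2060), 152 (YPS2067). A spline with 9 degrees of freedom gave for varying with time 281 (YPS2066), 305 (YPS2067), 18 (YPS2079), 153 (YPS3060), 179 (YPS3137) and for time course 52 (YPS183), 26 (YPS2067), 62 (YPS3060), 78 (YPS3137). Samples on 2007 prints alone gave for varying with time 657 (YPS183), 539 (YPS2055), 226 (YPS2060), 738 (YPS2066), 1051 (YPS2067), 146 (YPS2079), 539 (YPS3395), for level 92 (YPS2055), 5 (YPS2067) and for time course 101 (YPS183), 12 (YPS2055), 15 (YPS2060), 139 (YPS2066), 248 (YPS2067), 8 (YPS2079), 200 (YPS3395). That setting left out YPS2073, YPS3060 and YPS3137, and of the strains kept only YPS183 lost samples. The share of 2007 prints as a covariate gave for varying with time 40 (YPS2060), 50 (YPS2079), for level 20 (YPS2055), 3 (YPS2060), 8 (YPS2067), 344 (YPS2073), 7 (YPS3060) and for time course 54 (YPS3137). Leaving out samples lacking a dye swap gave for varying with time 27 (YPS2060), 184 (YPS2066), 52 (YPS3060), for level 10 (YPS3060) and for time course 2 (YPS2060), 40 (YPS2066), 14 (YPS3060). Weights by number of arrays gave for varying with time 295 (YPS183), 367 (YPS2055), 112 (YPS2060), 262 (YPS2066), 96 (YPS2079), 137 (YPS3060), 159 (YPS3137) and for time course 9 (YPS2055), 4 (YPS2060), 5 (YPS2079), 47 (YPS3137). YPS183 as the baseline gave for level 249 (YPS2055), 223 (YPS2060), 297 (YPS2066), 196 (YPS2067), 370 (YPS2073), 265 (YPS2079), 193 (YPS3060), 239 (YPS3137) and for time course 13 (YPS2055), 11 (YPS2060), 32 (YPS2067), 106 (YPS2073), 10 (YPS2079), 8 (YPS3137), 52 (YPS3395). A strain-specific term for alternate sampling times gave for varying with time 438 (YPS183), 381 (YPS2055), 68 (YPS2060), 865 (YPS2067), 96 (YPS2079), 327 (YPS3060), 347 (YPS3137), 4139 (all strains) and for time course 37 (YPS183), 8 (YPS2055), 3 (YPS2060), 113 (YPS2066), 196 (YPS2067), 7 (YPS2079), 89 (YPS3060), 185 (YPS3137), 1092 (all strains). Set A alone with 3 degrees of freedom gave for level 52 (YPS2055), 41 (YPS2060), 94 (YPS2066), 11 (YPS2067), 97 (YPS2079), 172 (YPS3060), 285 (YPS3137). Set B alone gave for level 13 (YPS2060), 5 (YPS2067), 34 (YPS3137). Leaving out each time gave for varying with time 92 to 243 (YPS183), 140 to 217 (YPS2055), 0 to 40 (YPS2060), 13 to 39 (YPS2079), 51 to 313 (YPS3060), 53 to 281 (YPS3137), for level 19 to 39 (YPS2055), 2 to 13 (YPS2060), 1 to 4 (YPS2067), 6 to 65 (YPS3060) and for time course 10 to 36 (YPS183), 1 to 4 (YPS2055), 0 to 4 (YPS2060), 24 to 92 (YPS2067), 161 to 427 (YPS2073), 1 to 5 (YPS2079), 13 to 155 (YPS3060), 14 to 175 (YPS3137), 469 to 917 (all strains). Against YPS183 the difference turned for YRF1-4 (-0.70) and YRF1-6 (-0.92) in YPS2055, YNL054W-A (-0.15) and ZRT1 (0.19) in YPS2060, and TIP1 (-0.27), YRF1-7 (-0.62) and AGP1 (-1.51) in YPS3137. Within set B it turned for EKI1 (0.0151) and IBD2 (0.0425) in YPS3060 and AGP1 (-0.18) and PIM1 (0.061) in YPS3137.

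Filters on missing values were not run, since no value was missing. The timing alternatives fixed before were run on all measured members, since the fixed gene choice left none. Median centring and the series matrix table moved no count of a comparison by over 1.5 times. Signal over background was not analysed here, so what dim spots limit is unknown.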

Other observations

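Other lists gave little at release by limma. Of 39 copy number variable genes 0 passed, with 8 at an unadjusted p under 0.05. The same counts were 0 and 3 of 30 respiratory chain, 0 and 2 of 19 S/G2, 0 and 1 of 15 iron uptake, 0 and 1 of 15 phosphate and 0 and 1 of 11 gluconeogenesis genes. They were 0 and 0 of 21 sulfate and methionine, of 14 meiosis, of 6 flocculin, of 5 cold mannoprotein and of 1 alpha mating type genes. Of 33 amino acid genes 1 rose, LEU9 (0.58), and of 138 ribosomal protein genes only RPS28B rose (0.86).

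In the time course model some metabolic genes differed in level in YPS3395, though their lists did not pass with an estimated correlation. FET3, the iron oxidase, was lower (-1.67 ± 0.16, SE, 1 culture), FTR1 differed by -1.28, and 4 of 15 iron uptake genes were at least 1 lower (list adjusted p = 0.426 with an estimated correlation). Of 21 sulfate and methionine genes 7 were at least 1 lower, with MET14 at -1.78 and SUL1 at -1.68 (adjusted p = 0.441 with an estimated correlation). In YPS2055 GPH1 (-1.19) and HSP12 (-1.07) of the stress list were lower (adjusted p = 0.110 with an estimated correlation).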
